A study of Pinctada imbricata with 5 samples.

How the data were processed

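Gene expression was measured by digital gene expression profiling, a method that counts short tags cut from messenger RNA, in the pearl sac of a pearl oyster. The pearl sac is the pouch of epithelium that grows from a piece of donor mantle around an implanted nucleus and lays down the pearl. Per the labels, sacs were taken on days 10, 15, 20, 30 and 60 after surgical implantation from oysters 1.5 years old, and total RNA was extracted with Trizol. The sample labels give the species as Pinctada imbricata and the series title as Pinctada martensii. There was 1 library per day, so 5 libraries in all, and the labels do not say how many sacs went into each.

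The deposited table of each library lists unigenes, that is assembled transcripts. For every unigene it gives a count, which per the file headers and the values is the sum of the copies of its tags, as whole numbers with no normalization. It also gives a TPM value, which by the values the authors computed as the count over a total of tags per library, with no correction for transcript length. Each unigene further has its best protein match in the nr database, its gene ontology terms, and the sequence of every tag with the tag count and the number of its CATG site from the 3′ end of the unigene, per the file headers. All tags were 21 bases long and began with CATG. The labels name a TruSeq RNA kit, which does not produce such tags, so the values were treated as tag counts as the tables show them. No listed tag had fewer than 2 copies, so a gene that is not listed may have had a tag seen once. Each tag belonged to 1 unigene. The aligner, the number of mismatches allowed and the assembly are not given in the sources used here, and no genome was used, so no positions are given.

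The total number of tags behind each library was recovered as count divided by TPM over genes of at least 5000 tags. It came to 4731837 on day 10, 4777386 on day 15, 4784094 on day 20, 4700927 on day 30 and 4743307 on day 60. The tags listed for unigenes summed to between 600848 and 1339346 per library, 12.8% to 28.0% of those totals. Scaling factors on the recovered totals were computed over the 5 libraries together with TMM in edgeR 4.0.16 (R 4.3.3) and were 0.948, 1.16, 0.902, 0.878 and 1.15 in order of day. Scaled TPM is the TPM divided by the factor of its library. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

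Consecutive days were compared (day 15 with 10, 20 with 15, 30 with 20, 60 with 30), and the last day with the day 10 library. The following choices were made before the data were examined. A gene counted as higher or lower when it had at least 10 scaled TPM in the higher library, which is 41.3 to 55.5 tags, and when the whole 95% interval of its ratio lay beyond 2-fold. The interval was the Clopper-Pearson interval conditional on the gene's 2 counts. A gene peaked on a day when it met the same rule against each of the other 4 days. With 1 library per day nothing measures the spread between oysters or between library preparations, so there was no test between days and no p-value. Intervals and floors cover counting error only. Where a gene was not listed in the lower library, the fold is given against a floor of 3 tags and written as at least that fold. The floor is a convention and not the 95% limit of the ratio, which is somewhat lower, for example 378-fold where the floor gives 465-fold (Unigene1470, day 15 against 10).

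Gene lists were defined by patterns over the protein match. The 22 lists covered nacre matrix, prism matrix, mantle genes, silk and glycine-rich proteins, calcium and carbonate handling, chitin, BMP and TGF-beta signalling, extracellular matrix, immune, stress and redox, cell division, cell death, and ribosomal proteins. Markers of other cell types were muscle, sperm and motile cilia, egg and germline, hemocyte, digestive gland and nervous. Signs of RNA quality were proteins of the mitochondrial genome and ribosomal RNA, and the last list was of mobile elements. Members needed 10 scaled TPM in at least 1 library. A list of 5 or more members was given a median log2 ratio of scaled TPM plus 1 and its percentile among 10000 random lists of equal size drawn from 10 bins of mean expression. The percentile is a description of these libraries. Lists of fewer members were given counts of members that were higher or lower. For 7 lists (silk and glycine-rich, chitin, cell death, egg and germline, mitochondrial genome, ribosomal RNA and mobile elements) no member reached 10 scaled TPM, and they gave no result. No unigene at all matched the silk, mitochondrial genome and ribosomal RNA patterns, so the lists gave no check of RNA quality. A few members matched the pattern by another word, such as an actin of the mosquito Psorophora ciliata in the sperm and motile cilia list. Such lists were counted again without them, and the median was computed again where 5 or more members were left. The sperm and motile cilia list kept 4 members without the actin, so it was given counts and no median.

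The genes named in the text were taken by rule from those whose match names a protein. These were the 12 higher and the 12 lower genes of each comparison with the interval bound farthest from 1, the 5 such genes peaking on each day, all members of the nacre, prism, mantle and chitin lists, the 4 members of every other list with the highest mean, and the 10 most abundant genes of each library. Matches that carry only a gene model identifier qualified by this rule and were passed over in the text. Other list members were named only as examples of a list count and were chosen after their values were seen, as were genes followed from one comparison into another.

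Alternatives planned with the rule were total tags or DESeq2 1.42.0 size factors in place of TMM, a minimum of 1 or 50 scaled TPM or none in place of 10, a bound of 4-fold, a 99% interval, libraries thinned to the smallest listed total, the authors' TPM with a 4-fold threshold and no interval, pseudocounts of 0.1 and 5, and detection at 10 tags. Alternatives chosen after seeing the data were TMM on the listed totals, unlisted genes counted as 1 tag, tags of the 3′-most site alone, libraries thinned to 479908 tags without Unigene51171, peaks without the day 15 library, lists without members matched by another word, and lists with members under 3 tags set at 3 tags. Lists with members of 1 scaled TPM or more were also counted after seeing the data. The counting rule was tested on simulated data with the depth of these libraries and with counting error alone. Of 100 genes changed 4-fold, 94 to 99 were recovered in each comparison, and none of the unchanged genes was called. The unchanged genes were set at exactly 1-fold, with no spread between oysters or library preparations. The simulation therefore cannot tell how many real calls come from such spread.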

Results

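Tag profiles of the pearl sac were compared at 5 times after implantation, 10, 15, 20, 30 and 60 days, with 1 library at each time. The series title gives the search for candidate genes of nacre formation as the purpose. In the 5 libraries together 19415 unigenes were listed, of which 3885 were listed on every day. A protein match was given for 5341 of them (27.5%). The number of unigenes listed was 9586 on day 10, 11675 on day 15, 8824 on day 20, 9243 on day 30 and 10456 on day 60, and after thinning to 600848 tags per library it was 9221, 11093, 7902, 9243 and 10375.

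A single unigene, Unigene51171, took the largest share of the listed tags in every library. It had 403032 tags on day 10 (43.2% of the listed tags), 366268 on day 15 (37.7%), 805003 on day 20 (60.1%), 120940 on day 30 (20.1%) and 224102 on day 60 (31.2%). Its best match was a vacuolar sorting protein 13D of chicken with an e-value of 2.44e-07. The next most abundant genes with a named match included ribosomal proteins L23a (Unigene61228), with 2946 to 10252 tags per library, and L9 (Unigene23715), with 3846 to 6705. Most of the abundant unigenes had no match, among them Unigene13576, which had 31973 tags on day 10, 46487 on day 30 and 0, 11 and 2 on days 15, 20 and 60.

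Across genes, the most alike pair of libraries was day 10 with day 30 (Spearman's rho 0.607), which are not neighbouring days. The 4 pairs that include day 15 had the lowest values, from 0.396 with day 60 to 0.450 with day 10, and the other 5 pairs lay between 0.519 and 0.562. Genes are not independent replicates, and these values carry no test. Among genes of at least 10 scaled TPM in some library, rho for days 10 and 30 was 0.714.

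Between day 10 and day 15, several genes of shell formation fell and several of cilia rose. All 4 members of the nacre matrix list were lower on day 15. PIF (Unigene83722), a matrix protein that binds aragonite in nacre, was 39.6-fold lower (95% interval 16.6 to 124), nacre protein Unigene14842 was 19.3-fold lower (7.93 to 61.1) and Unigene72742 at least 90.4-fold lower. Tyrosinase-like protein 1 (Unigene1470), of an enzyme family that crosslinks the organic matrix of the prismatic layer, fell from 1127 tags to none listed, at least 465-fold. Of the 7 mantle genes, mantle gene 5 (Unigene39109) and mantle protein 10 (Unigene59335) fell, at least 63.1-fold and 64.8-fold, and the other 5 neither rose nor fell by the rule (median -0.15, percentile 49.2).

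Of the 5 members of the sperm and motile cilia list, 4 rose. Axonemal dynein heavy chain 5 (Unigene82585), a motor of ciliary beating, was 22.1-fold higher (13.5 to 39.0), and a sperm autoantigenic protein 17 match (Unigene88198) 21.8-fold (9.12 to 68.2). Radial spoke proteins 3 (Unigene73085) and 1 (Unigene81707), which regulate the axoneme, rose from 3 to 64 and from 2 to 59 tags. The list's median log2 ratio was 3.01, at percentile 97.9 of random lists, 4.11 with members of fewer than 3 tags set at 3, 1.54 with a pseudocount of 5, and 1.74 over the 13 members of 1 scaled TPM or more, of which 7 rose and 1 fell. The interval of the median, taken from the ordered members, was -2.17 to 4.13, and for all lists given a median and all 5 comparisons this interval spanned 0. With 5 members the interval ran from the lowest to the highest of them. The member that was not higher was the mosquito actin, which set the lower end of the interval. Without it 4 of 4 members rose. Beta-tubulin (Unigene18140), the partner of alpha-tubulin in microtubules, was 22.8-fold higher (16 to 33.8), and the armadillo repeat containing 4 match (Unigene89946), a protein of ciliary dynein arms, 31.8-fold (17.1 to 66.9).

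In the immune list 7 of 13 members were lower on day 15 and 2 were higher, with a median of -1.83 (percentile 0.485). The interval of that median was -3.87 to 1.12. Over the 27 members of 1 scaled TPM or more, 9 were lower and 2 higher, and the median was -0.53. A complement C1q-like protein (Unigene91786) was 20.5-fold lower (9.65 to 52.2), thioester-containing protein F (Unigene38628), a complement-like opsonin, 20.1-fold lower (8.25 to 63.4), and a galactose-binding lectin (Unigene75519) at least 71.8-fold lower. The 2 that rose were the galectin-4 match (Unigene89194), 24.7-fold (14.6 to 45.7), and peptidoglycan recognition protein L (Unigene88153), 3.91-fold (2.13 to 7.75). Allograft inflammatory factor 1 (Unigene89534), the only member of the hemocyte list and also in the immune list, was 6.13-fold lower (5.12 to 7.39). Here and in the following comparisons, list members other than those fixed by the rule for named genes were chosen as examples after their values were seen, and so were genes followed from the comparison that named them into another.

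Unigenes matching Kazal-type inhibitors, which block serine proteases, went from 1697 tags to none listed (Unigene80425, at least 700-fold lower) and from 304 to none (Unigene71003, at least 125-fold). An antistasin match (Unigene58429), also an inhibitor, fell at least 394-fold and a follistatin-like protein (Unigene53180) 280-fold (109 to 1030). A serine proteinase match (Unigene38190) rose from 34 to 15077 tags, 358-fold (256 to 517), and another (Unigene63907) at least 116-fold. CD151 antigen (Unigene87984), a tetraspanin that associates with integrins, rose 88.8-fold (24.3 to 738) and annexin A11 (Unigene84692) 54.1-fold (24.6 to 148). Non-muscle actin (Unigene21986) fell 136-fold (86.7 to 226), and the other member of the muscle list, non-muscle myosin heavy chain 10 (Unigene69362), had a ratio of 1.32 (0.849 to 2.06). Both matches are to non-muscle proteins, so at this level the list held no marker of muscle. Another unigene with the same actin match (Unigene79561), under the minimum level, had 36, 40, 38, 16 and 16 tags in order of day. Pyruvate kinase (Unigene81583), of glycolysis, rose at least 28-fold and a kelch-like 26 match (Unigene46952) at least 23.2-fold, and an ADP-ribosylating protein CARP-1 match (Unigene88974), the import translocase TIM44 (Unigene82768) and a G protein-coupled receptor (Unigene89256) fell at least 112-fold, 89.2-fold and 82.5-fold.

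In the calcium and carbonate list, 1 unigene matching calmodulin (Unigene91212), the calcium sensor of most cells, rose from 2 to 104 tags, 42.0-fold (11.3 to 351). Calreticulin (Unigene90482), a calcium-binding chaperone, rose 6.73-fold (3.69 to 13.5), while alkaline phosphatase and calcineurin B did not pass the rule. Other calmodulin matches, under the minimum level, had 20, 15, 19, 12 and 16 tags (Unigene91150) and 0, 7, 0, 6 and 7 (Unigene10986) in order of day. Of 11 stress and redox members 3 rose and 1 fell (median 0.52, percentile 83.3). HSP90 (Unigene83137) rose 7.73-fold (3.55 to 20.0) and mitochondrial HSP60 (Unigene89867) 11.8-fold (4.83 to 37.4), and microsomal glutathione S-transferase (Unigene88179) fell 4.95-fold (2.72 to 9.63). The member that also rose, heat shock factor 2 binding protein (Unigene86418), is not itself a heat shock protein. Its rise did not pass the rule with tags of the 3′-most site alone. Of 14 ribosomal genes 4 rose and 0 fell (median 0.48, percentile 96.2, interval -0.07 to 1.72), and all 4 were mitochondrial, so that the 8 cytosolic members had a median of -0.04. Geminin (Unigene4604), which keeps DNA from being copied again in the same cycle, rose 3.57-fold (2.62 to 4.95), 1 of 3 cell division members. Integrin beta-1 (Unigene20091), of the extracellular matrix list, fell 8.36-fold (3.95 to 20.3), and the single digestive gland member, a pancreatic lipase-related protein (Unigene92137), fell 2.98-fold (2.06 to 4.38). No member of the BMP and TGF-beta list (2) or the nervous list (2) passed the rule.

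In all, 339 genes were higher and 400 lower on day 15, of 1669 compared. Of these, 73 and 44 had a match that named a protein. Scaling by total tags moved all log2 ratios by 0.29 and the share of higher genes from 45.9% to 59.5%. Tyrosinase-like protein 1, Kazal inhibitor Unigene71003, CD151 and calmodulin did not pass the rule with tags of the 3′-most site alone.

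From day 15 to day 20 several genes of cilia and of calcium handling fell. Axonemal dynein heavy chain 5 (Unigene82585) was 18.9-fold lower (11.8 to 32.2) and the sperm autoantigenic protein 17 match (Unigene88198) at least 35.0-fold lower, among 4 of 5 sperm and motile cilia members that fell. The list's median was -2.99 (percentile 4.25, interval -4.66 to 3.24), and -1.74 over the 13 members of 1 scaled TPM or more. The member that rose was the mosquito actin, which set the upper end of the interval. Beta-tubulin (Unigene18140) fell 61.9-fold (34.4 to 125) and the armadillo repeat containing 4 match (Unigene89946) at least 102-fold. Of 4 calcium and carbonate members 3 fell, calmodulin (Unigene91212) at least 26.9-fold, calreticulin (Unigene90482) 11.1-fold (5.19 to 28.3) and calcineurin B (Unigene90071), the regulatory subunit of a calcium-dependent phosphatase, 9.0-fold (5.82 to 14.6). The member that rose was alkaline phosphatase (Unigene7396), an enzyme used as a marker of mineralizing tissue, from none listed to 44 tags, at least 18.9-fold. At 1 scaled TPM or more 4 of 12 members fell and 1 rose.

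Collagen IV alpha 1 (Unigene90525), the main collagen of basement membranes, rose 15.1-fold (11.7 to 19.9), with nearly all of its day 20 tags at a CATG site other than the 3′-most, and a collagen XXI match (Unigene1683) 5.70-fold (3.16 to 11), so that 2 of 3 extracellular matrix members were higher and 0 lower. Among the mantle genes, 3 of 7 rose. Mantle gene 1 (Unigene89281) went from 47 to 450 tags, 12.3-fold (9.11 to 17), and 1 unigene matching mantle gene 4 (Unigene29181) was at least 32.2-fold higher, while another (Unigene79830) fell 9.79-fold (3.98 to 31.2). The rise of mantle gene 1 did not pass the rule with tags of the 3′-most site alone. The median of the mantle list was 0.00 with percentile 52.0. It was set by members unlisted on both days, so it is not a measured lack of change. Nacre protein Unigene14842 rose 28.6-fold (11.9 to 89.7), and the other 3 nacre members, PIF included, did not pass the rule. Neither day listed tyrosinase-like protein 1 (Unigene1470).

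Of the heat shock proteins, which are chaperones, some rose and others fell. Unigenes matching the 70 kDa family rose from 3 to 109 tags (Unigene65737, 46.8-fold, 15.6 to 230) and from none to 86 (Unigene11712, at least 36.9-fold). Other matches to this family were under the minimum level. The match to HSP70 of Pinctada fucata (Unigene50476) had 7, 8, 15, 6 and 9 tags in order of day. Unigene69586 had 0, 7, 20, 0 and 4, and Unigene20283 had 2, 0, 0, 0 and 12. Alpha-crystallin B (Unigene85224), a small heat shock protein, rose 22.7-fold (10.1 to 63.4), while HSP90 (Unigene83137) fell 5.20-fold (2.66 to 11.3), mitochondrial HSP60 (Unigene89867) 5.16-fold (2.72 to 10.8) and HSP10 (Unigene20937) 3.76-fold (2.64 to 5.48). A heat shock factor 2 binding protein (Unigene86418) fell 46.7-fold (21.3 to 128). Counts for the stress list were 3 higher and 4 lower of 11, with a median of 0.00 (percentile 57.0), set by a member unlisted on both days. They were 3 and 3 of 9 with a median of 1.37 without the members matched by another word. Dual oxidase 1 (Unigene52584), which makes hydrogen peroxide at cell surfaces, was at least 46.8-fold higher, an NFX-type transcription factor (Unigene54522) at least 283-fold, the G protein-coupled receptor (Unigene89256) at least 86.7-fold, a protein lethal match (Unigene78219) 115-fold (39.1 to 563) and asparagine synthetase (Unigene1187) at least 24.0-fold. Ribosomal protein L22e (Unigene79656) rose 41.0-fold (31.1 to 55.2). Of 14 members of the ribosomal list 3 rose and 5 fell, with a median of -0.41 (percentile 15.2). The 5 that fell were among 6 mitochondrial ribosomal proteins, and the other 8 had a median of 0.92.

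The serine proteinase Unigene38190 fell from 15077 tags to 4, 2928-fold (1143 to 10748), and Unigene63907 at least 112-fold. Annexin A11 (Unigene84692) fell 44.6-fold (21.5 to 112) and CD151 (Unigene87984) 57.0-fold (19.2 to 278). A transcription factor with NAC and TS-N domains (Unigene71884) went from 627 tags to none listed, at least 162-fold lower, and NADH dehydrogenase 1 beta subcomplex 7 (Unigene73343), of the respiratory chain, fell at least 24.3-fold. Among 13 immune genes 3 fell and 1 rose, with a median of 0.00 (percentile 56.1). C1q domain protein 2 (Unigene86498) fell 9.65-fold (6.76 to 14.2), and the C1q-like protein Unigene91786 rose 8.64-fold (3.88 to 22.7). Neuronal calcium sensor (Unigene13560), 1 of 2 nervous members, rose at least 21-fold. In the cell division list the condensin II subunit D3 (Unigene90453) rose 3.71-fold (2.32 to 6.10) and DNA polymerase alpha subunit B (Unigene64641) fell 3.36-fold (2.21 to 5.26). Non-muscle actin (Unigene21986) rose 22.8-fold (14.4 to 38.4), 1 of 2 in the muscle list, and the hemocyte, digestive gland and BMP members did not pass the rule.

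In all, 410 genes were higher and 441 lower on day 20, of 1625 compared. Scaling by total tags moved all log2 ratios by -0.37 and the share of higher genes from 48.2% to 34.8%, and alkaline phosphatase then fell under the minimum level. The NFX-type factor, CD151, heat shock factor 2 binding protein and calmodulin did not pass the rule with tags of the 3′-most site alone.

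**Figure D1:**
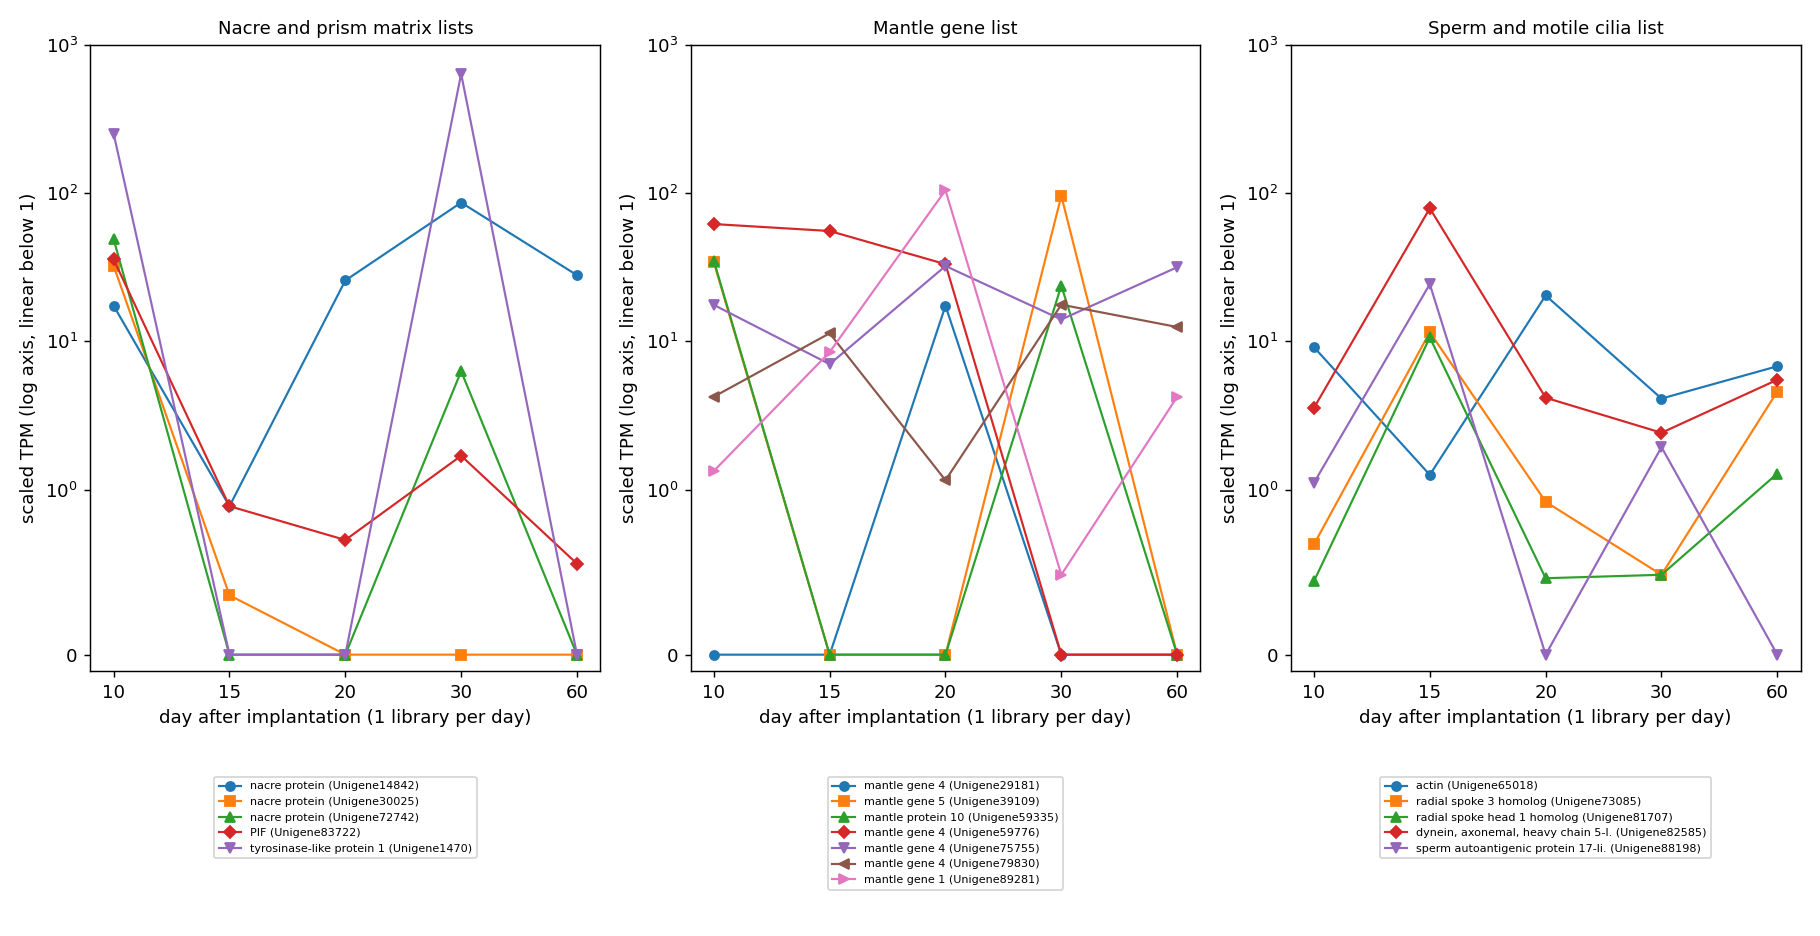
Scaled TPM (log axis, linear below 1) of every gene of at least 10 scaled TPM in the nacre and prism matrix lists (left), the mantle gene list (middle) and the sperm and motile cilia list (right) on each sampled day, with 1 library per day, so that lines join single values and no error is drawn. Tyrosinase-like protein 1 (Unigene1470) stood at 251 and 635 scaled TPM on days 10 and 30 and at 0 on the other days, and axonemal dynein heavy chain 5 (Unigene82585) at 78.9 on day 15 against 2.42 to 5.51 on the other days.

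Between day 20 and day 30 several shell genes that were unlisted on days 15 and 20 were listed again. Tyrosinase-like protein 1 (Unigene1470) went from none listed to 2622 tags, at least 913-fold higher. Mantle gene 5 (Unigene39109) rose at least 138-fold and mantle protein 10 (Unigene59335) at least 34.1-fold, whereas mantle gene 1 (Unigene89281) fell 215-fold (59.3 to 1783) and the mantle gene 4 matches Unigene59776 and Unigene29181 at least 45.6-fold and 23.9-fold. Thus 3 of the 7 mantle genes rose and 3 fell, with a median of -1.14 (percentile 3.24, interval -6.15 to 6.60). In the nacre list Unigene14842 rose 3.35-fold (2.70 to 4.19) and 3 of 4 did not pass the rule. PIF (Unigene83722) had 3 and 7 tags.

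Of 13 immune genes 6 were higher on day 30 and 0 lower, with a median of 1.56 (percentile 99.7). The interval of that median was -0.25 to 2.26, and over the 27 members of 1 scaled TPM or more 7 were higher and 1 lower, with a median of 0.10. Without a ubiquitin thioesterase that matched the pattern by another word the median was 0.86. Allograft inflammatory factor 1 (Unigene89534), also the hemocyte member, rose 4.89-fold (4.10 to 5.86). The jacalin-related lectin Unigene2003 rose 5.34-fold (2.58 to 12.4) and another (Unigene91750) at least 17.4-fold, C1q domain protein 2 (Unigene86498) 3.74-fold (2.52 to 5.68) and peptidoglycan recognition protein L (Unigene88153), which senses bacterial walls, 6.74-fold (3.55 to 14.1).

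Matches to Kazal-type inhibitors, unlisted on days 15 and 20, rose to 563 tags (Unigene80425, at least 196-fold) and 246 tags (Unigene71003, at least 85.7-fold), and the antistasin match (Unigene58429) rose at least 488-fold. Follistatin-like protein (Unigene53180) rose 8.11-fold (6.03 to 11.1), the NAC and TS-N factor (Unigene71884) at least 544-fold and histone H4 (Unigene84421) at least 31-fold. TIM44 (Unigene82768), the transcription factor Tal (Unigene91923), a band 4.1-like 3 match (Unigene16467) and CARP-1 (Unigene88974) rose at least 33.8-fold, 33.8-fold, 25.4-fold and 19.2-fold. Beta-tubulin (Unigene18140) rose 19.9-fold (10.9 to 40.4). The sperm and motile cilia list had a median of -0.38 (percentile 24.7), with 1 member lower, the mosquito actin, and none higher.

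Collagen IV alpha 1 (Unigene90525) fell 16-fold (11.8 to 22.1) and the collagen XXI match (Unigene1683) 19.8-fold (6.46 to 98.5), which made 2 of 3 matrix members lower. HSP70 matches fell at least 34.8-fold (Unigene65737) and 27.4-fold (Unigene11712) and alpha-crystallin B (Unigene85224) 16.9-fold (7.51 to 47.1), so that 3 of 11 stress members fell and 0 rose (median -0.21, percentile 26.3, and -0.75 without members matched by another word). Alkaline phosphatase (Unigene7396) was again unlisted, at least 14-fold lower, the only 1 of 4 calcium members that passed. Calcium homeostasis endoplasmic reticulum protein (Unigene68223) fell 45.9-fold (15.4 to 225) and monoamine oxidase A (Unigene1820), which breaks down amine transmitters, at least 17.5-fold. The protein lethal match (Unigene78219) fell 14.3-fold (8.88 to 24.5). Neuronal calcium sensor (Unigene13560, nervous) fell at least 15.6-fold, the lipase-related protein (Unigene92137, digestive gland) 4.53-fold (2.57 to 8.51), non-muscle myosin (Unigene69362, muscle) 5.65-fold (2.86 to 12.4) and ribosomal protein S10 (Unigene86218) 2.14-fold (2.03 to 2.25). That was the only 1 of 14 ribosomal genes to pass, and the list's median was 0.10 (percentile 71.3), and -0.44 over the 8 cytosolic members. No BMP or cell division member passed.

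In all, 307 genes were higher and 286 lower on day 30, of 1523 compared, and 94 of the higher genes were unlisted on day 20. Tyrosinase-like protein 1, Kazal inhibitor Unigene71003, mantle gene 1, band 4.1-like 3 and collagen IV alpha 1 did not pass the rule with tags of the 3′-most site alone, where the log2 ratio of collagen IV (Unigene90525) was -0.55. Ribosomal protein S10 (Unigene86218) had no tag at that site, so its fall could not pass there. Alkaline phosphatase was under the minimum level with total tags or thinned libraries.

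From day 30 to day 60 several shell genes fell again, and geminin and dual oxidase C rose. Tyrosinase-like protein 1 (Unigene1470) went from 2622 tags to none listed, at least 1152-fold lower, mantle gene 5 (Unigene39109) fell at least 174-fold and mantle protein 10 (Unigene59335) at least 43.0-fold. Nacre protein Unigene14842 fell 3.09-fold (2.55 to 3.76). Thus 1 of 4 nacre members and 2 of 7 mantle genes were lower and none higher. The mantle list's median was 0.00 (percentile 51.3), set by a member unlisted on both days. Geminin (Unigene4604) rose from 119 to 1194 tags, 7.61-fold (6.30 to 9.27), the only 1 of 3 cell division members to pass, and dual oxidase C (Unigene70251) from 9 to 567, 47.8-fold (25 to 105).

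The same Kazal-type matches fell to 2 tags (Unigene80425, 371-fold, 102 to 3071) and to none (Unigene71003, at least 108-fold), and the antistasin match (Unigene58429) at least 616-fold. Follistatin-like protein (Unigene53180) fell at least 170-fold, the NAC and TS-N factor (Unigene71884) at least 686-fold and ribosomal protein L22e (Unigene79656) from 1540 to 10 tags, 203-fold (110 to 424). TIM44 (Unigene82768), the band 4.1-like 3 match (Unigene16467) and CARP-1 (Unigene88974) fell at least 42.6-fold, 32.1-fold and 24.2-fold. L22e and S10 (Unigene86218, 3.24-fold, 2.99 to 3.51) were the 2 of 14 ribosomal genes that fell. The median of that list was 0.02 (percentile 48.1), -0.03 with DESeq2 size factors and -0.11 over the 8 cytosolic members.

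Dipeptidyl-peptidase 10 (Unigene83891) rose at least 37.9-fold, and low density lipoprotein receptor-related protein 6 (Unigene92669), a co-receptor of Wnt signals, at least 27.6-fold. The 26S protease regulatory subunit 6B (Unigene75762), part of the proteasome, rose 17.7-fold (5.81 to 87.9), and a cytochrome P450 match (Unigene90531), of a family of detoxifying oxidases, at least 14.2-fold. An RNA binding protein (Unigene21193), an XPA binding protein 2 match (Unigene19911) and a Blo t 13 allergen match (Unigene86436), of a fatty acid binding family, rose at least 17.2-fold, at least 15.9-fold and 10.9-fold (4.47 to 34.7). With the P450, a thioredoxin-domain protein (Unigene21280, 2.78-fold, 2.22 to 3.51) and alpha-crystallin B (Unigene85224, 8.73-fold, 3.81 to 24.6), 3 of 11 stress members rose and 0 fell, with a median of 0.88 (percentile 97.1, interval -0.32 to 2.48). Over the 46 members of 1 scaled TPM or more, 5 rose and 2 fell, and the median was 0.48. Of 13 immune genes 1 fell, jacalin-related lectin Unigene2003, and the median was -0.39 (percentile 17.3). The sperm and motile cilia list had a median of 0.62 (percentile 85.5) with no member past the rule. Non-muscle myosin (Unigene69362, muscle) rose 4.33-fold (2.19 to 9.50). No member of the calcium, BMP, matrix, hemocyte, digestive gland or nervous lists passed.

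In all, 237 genes were higher and 234 lower on day 60, of 1525 compared, and 82 of the lower genes were unlisted on day 60. Scaling by total tags moved all log2 ratios by 0.39 and gave 373 higher genes, 69.6% of those that passed, against 50.3% with TMM. Tyrosinase-like protein 1, Kazal inhibitor Unigene71003, the RNA binding protein and band 4.1-like 3 did not pass the rule with tags of the 3′-most site alone. The rise of alpha-crystallin B (Unigene85224) did not pass there either. Nor could the fall of ribosomal protein S10 (Unigene86218), which had no tag at that site.

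Over the whole interval, day 60 against day 10, several genes of shell formation were lower and geminin and dual oxidase C higher. PIF (Unigene83722) was 64.7-fold lower (21.7 to 317), nacre proteins Unigene72742 and Unigene30025 at least 88.6-fold and 58.6-fold, and Unigene14842, with 78 and 152 tags, had a ratio of 1.61 (1.21 to 2.14). The tyrosinase-like protein (Unigene1470) was at least 456-fold lower, and 3 of 7 mantle genes were lower with none higher, mantle gene 4 (Unigene59776) by at least 112-fold. The median of the mantle list was 0.00 (percentile 60.4), set by a member unlisted on both days. Kazal-type inhibitor Unigene80425 went from 1697 to 2 tags, 1029-fold lower (285 to 8506).

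The antistasin match (Unigene58429) was at least 386-fold lower, follistatin-like protein (Unigene53180) at least 366-fold and a galactose-binding lectin (Unigene75519) at least 70.4-fold. Kazal-type inhibitor Unigene71003, CARP-1 (Unigene88974), TIM44 (Unigene82768), a venom protein M match (Unigene83268) and the NAC and TS-N factor (Unigene71884) were lower by at least 123-fold, 110-fold, 87.3-fold, 71.2-fold and 67.5-fold. With the lectin, 5 of 13 immune genes were lower and 1 higher, with a median of -0.63 (percentile 13.7). Peptidoglycan recognition protein L (Unigene88153) was 7.10-fold higher (3.99 to 13.8). Calcineurin B (Unigene90071) was 4.35-fold lower (2.96 to 6.57), the lipase-related protein (Unigene92137) 8.17-fold (4.72 to 15.1) and non-muscle actin (Unigene21986) 4.12-fold (3.76 to 4.51).

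Geminin (Unigene4604) was 19.7-fold higher (14.8 to 26.7) and condensin II subunit D3 (Unigene90453), which compacts chromosomes, 3.79-fold (2.68 to 5.48), 2 of 3 cell division members. Dual oxidase C (Unigene70251) was 23.4-fold higher (15.0 to 38.6) and a cytochrome c oxidase subunit IV match (Unigene85613), of the respiratory chain, 5.77-fold (5.00 to 6.70). Alpha-crystallin B (Unigene85224) was 28.4-fold higher (7.58 to 240), the thioredoxin-domain protein (Unigene21280) 5.58-fold (4.18 to 7.60) and the P450 (Unigene90531) at least 15.4-fold, so that 3 of 11 stress genes were higher and 0 lower (median 0.63, percentile 95, interval -0.19 to 3.24). Over the 46 members of 1 scaled TPM or more the median was 0.11, with 3 higher and 0 lower. Adenosine deaminase (Unigene89607), of purine breakdown, was 7.29-fold higher (4.10 to 14.1), an RNase H family match (Unigene80996) 20.9-fold (6.88 to 104), a thrombin match (Unigene83879) 10.6-fold (6.15 to 19.8), and the Blo t 13 match (Unigene86436) and XPA binding protein 2 (Unigene19911) at least 19.8-fold and 17.3-fold. Of 14 ribosomal genes 1 was higher and 2 lower, with a median of 0.35 (percentile 92.1), -0.04 when members needed 50 scaled TPM and 0.02 over the 8 cytosolic members. The sperm and motile cilia list had no member past the rule (median 0.51, percentile 85.4), and neither had the BMP, matrix, hemocyte and nervous lists.

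In all, 231 genes were higher and 304 lower on day 60 than on day 10, of 1602 compared, and 101 of the lower genes were unlisted on day 60. Scaling by total tags moved all log2 ratios by 0.28 and the share of higher genes from 43.2% to 56.0%. Alpha-crystallin B, tyrosinase-like protein 1 and Kazal inhibitor Unigene71003 did not pass the rule with tags of the 3′-most site alone.

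Genes that peaked on 1 day numbered 81 on day 10, 203 on day 15, 131 on day 20, 41 on day 30 and 82 on day 60. Day 10 peaks included PIF (Unigene83722, 160 tags against 3 to 7), nacre protein Unigene30025 (145 tags against 0 to 2) and the galactose-binding lectin (Unigene75519, 174 tags, unlisted on the other days), with the venom protein M match (Unigene83268) and a MEGF7 match (Unigene89191). Both serine proteinase matches (Unigene38190 and Unigene63907), CD151 (Unigene87984) and the armadillo repeat containing 4 match (Unigene89946) peaked on day 15. The HSP70 matches Unigene11712 and Unigene65737, mantle gene 1 (Unigene89281), mantle gene 4 (Unigene29181) and collagen IV alpha 1 (Unigene90525) peaked on day 20. Tyrosinase-like protein 1 (Unigene1470), nacre protein Unigene14842, mantle gene 5 (Unigene39109), the NAC and TS-N factor (Unigene71884) and histone H4 (Unigene84421) peaked on day 30, and geminin (Unigene4604), dual oxidase C (Unigene70251), the Blo t 13 match (Unigene86436) and the P450 (Unigene90531) on day 60. With tags of the 3′-most site alone, CD151, mantle gene 1, collagen IV alpha 1 and tyrosinase-like protein 1 did not meet the rule for these peaks.

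A further set of genes was above the other 3 days on both of 2 days by the same rule. There were 51 such genes for days 10 and 30 and 5 to 10 for each of the other 9 pairs. Of the 51, 24 were unlisted on days 15, 20 and 60. The 51 included tyrosinase-like protein 1, mantle gene 5, mantle protein 10, Kazal-type inhibitors Unigene80425 and Unigene71003, the antistasin match, follistatin-like protein and jacalin-related lectin Unigene2003. They made up 11.7% of the listed tags on day 10 and 15.8% on day 30. Unigene51171 is counted in those totals, at 43.2% and 20.1% of them, so the 2 shares do not have the same base. This count was chosen after the values were seen.

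**Figure D2:**
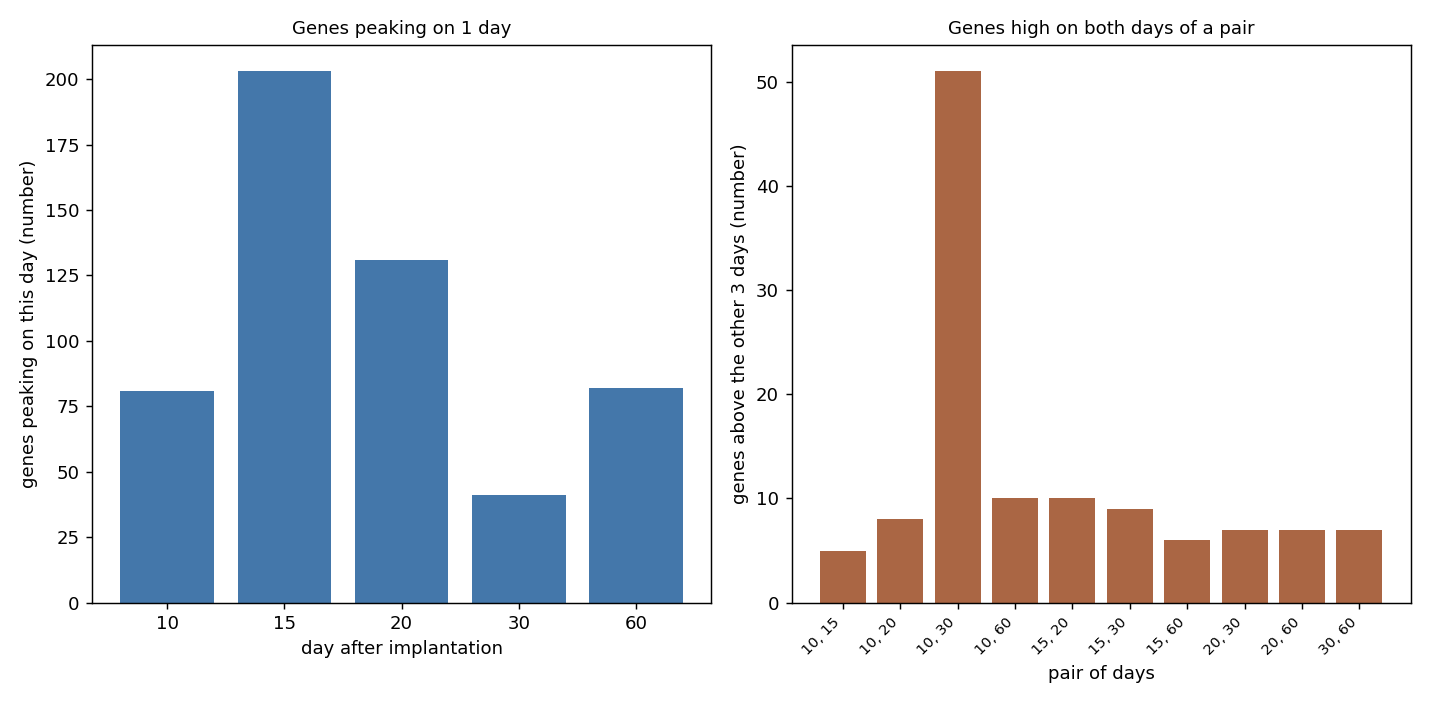
Number of genes that peaked on each day, at left, and number of genes above the other 3 days on both days of each pair, at right, with 1 library per day. Day 15 had the most peaking genes (203) and the pair of days 10 and 30 the most shared genes (51, against 5 to 10 for the other pairs).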

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

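The count of second tags and its threshold were chosen after the tag sequences were seen. The tag sequences themselves were not used in the comparisons. Of 739 tag sites with at least 100 tags in at least 2 libraries, 135 had a library-specific second tag, 1 base from the main tag. Such a tag made up at least 20% of the main and second tags together in some library and was not listed in another. The 2 tags together had at least 100 copies in both libraries. Counts and shares below leave out any other tags of the site. There were 150 second tags in 133 genes. They stood out because a signal appeared in data that no comparison used. Listed on a single day alone were 18 second tags on day 10, 9 on day 15, 10 on day 20, 3 on day 30 and 7 on day 60.

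The 3 with the most copies were in unigenes with no protein match, with positions counted from 1 at the C of CATG. Unigene13576 had the main tag CATGGGAACAAATGTGGATAC and the second tag CATGGGAACCAATGTGGATAC (A10C), with 10400 of 31183 tags on day 10 (33.4%, 95% Clopper-Pearson interval 32.8 to 33.9) and none listed beside 45505 on day 30. In Unigene10720 the second tag CATGTAATTTTGGTAGAGGTA (G14T against CATGTAATTTTGGGAGAGGTA) had 2023 of 2370 tags on day 10 and was not listed on days 15, 30 and 60, where the main tag had 4037, 977 and 2814. In Unigene67514 the second tag CATGTATAAGTATTTTTTAAA (C18T against CATGTATAAGTATTTTTCAAA) had 796 of 1150 tags on day 10, 551 of 554 on day 15, 10 of 1329 on day 20, 483 of 979 on day 60 and none beside 513 on day 30. Differences between the animals sampled on each day were not tested, since 1 library per day leaves the day and the animals as 1 factor.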

How the results depend on the processing

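Alternatives named as chosen after seeing the data in the account of the processing are meant here too. Most values without a replicate have no test, so a count was taken as kept when it stayed within 1.5 times its value under the chosen rule. Which of the 2 directions held more genes depended on the processing. On day 15 against 10 it was 339 higher and 400 lower, but 468 and 319 with total tags, 390 and 357 with DESeq2 size factors, 307 and 233 with the authors' TPM and 116 and 102 at 50 scaled TPM. On day 60 against 10 it was 231 and 304, but 332 and 261 with total tags and 192 and 192 with the authors' TPM. On day 30 against 20 it was 307 and 286, but 261 and 286 with total tags, 270 and 272 after thinning (303 and 284 when Unigene51171 was left out) and 80 and 94 at 50 scaled TPM. On day 60 against 30 it was 237 and 234, but 223 and 244 with DESeq2 size factors and 207 and 209 with a 99% interval, and more were lower at the other minimum levels and the 4-fold bound given below. Only on day 20 against 15 were more genes lower under every alternative. Medians of the ribosomal list changed sign, as given below, and 2 of 593 single genes between days 20 and 30 with tags of the 3′-most site alone. All counts of genes and peaks stayed within that range with DESeq2 size factors, a 99% interval, both ways of thinning, TMM on listed totals, unlisted genes counted as 1 tag, and tags of the 3′-most site alone. Of the 120 named gene and comparison pairs, 120 still passed with DESeq2 size factors, a 99% interval and a 4-fold bound, 117 with total tags and with the authors' TPM, 118 after thinning, with Unigene51171 in or left out, 99 with tags of the 3′-most site alone and 54 at 50 scaled TPM, where fewer genes were tested. These pairs were chosen for the interval bound farthest from 1, so passing a stricter bound or interval was largely fixed by that choice. Among all genes called, 409 of 739, 494 of 851, 323 of 593, 246 of 471 and 284 of 535 passed with the 4-fold bound, in the order of the comparisons. The ribosomal median changed sign on day 60 against 30 with DESeq2 size factors and on day 60 against 10 at 50 scaled TPM, and without the mitochondrial members it was -0.04, 0.92, -0.44, -0.11 and 0.02 in the order of the comparisons, against 0.48, -0.41, 0.10, 0.02 and 0.35 with them. Changes with the minimum level and the bound follow from their construction. For the others the cause was not tested.

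With a minimum of 1 scaled TPM, and equally with no minimum, the genes higher and lower were 796 and 1028 on day 15 against 10, 943 and 1020 on day 20 against 15, 794 and 607 on day 30 against 20, 508 and 645 on day 60 against 30, and 542 and 836 on day 60 against 10. Genes peaking on days 10, 15, 20, 30 and 60 were then 140, 365, 200, 87 and 135. At 50 scaled TPM the counts in the same order were 116 and 102, 124 and 136, 80 and 94, 55 and 68, and 55 and 86, with 21, 81, 48, 14 and 24 genes peaking. With the interval beyond 4-fold they were 181 and 228, 227 and 267, 184 and 139, 103 and 143, and 91 and 193, with 44, 121, 51, 14 and 26 genes peaking.

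With the authors' TPM at 4-fold and no interval, 233 genes were lower on day 15 than 10, 221 higher on day 20 than 15, 191 higher and 175 lower on day 30 than 20, 129 lower on day 60 than 30 and 192 lower on day 60 than 10, and 60 and 14 genes peaked on days 20 and 30. With total tags in place of TMM, 373 genes were higher on day 60 than 30 and 130 peaked on day 60. The median of the sperm and motile cilia list on day 15 against 10 was 3.01, 4.30 with a pseudocount of 0.1 and 1.54 with a pseudocount of 5. Over members of 1 scaled TPM or more, it was 1.74, and the immune medians were -0.53, 0.00, 0.10, -0.12 and -0.47 in the order of the comparisons, against -1.83, 0.00, 1.56, -0.39 and -0.63. For the stress list they were then 0.55, -0.59, 0.00, 0.48 and 0.11, against 0.52, 0.00, -0.21, 0.88 and 0.63. Spearman's rho of days 10 and 30 was 0.714 among genes of at least 10 scaled TPM. At 10 tags or more, 3493, 3854, 3130, 3192 and 3667 genes were listed in order of day.

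The DESeq2 size factors moved all log2 ratios of day 15 against 10 by 0.14. The listed tags numbered 600848 on day 30 and 1339346 on day 20, and without Unigene51171 the libraries held 479908 to 604456, so that depth apart from this gene differed little between days.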

Other observations

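All tests in this part, and the count of list members at 1 scaled TPM or more, were chosen after the results were seen. At that lower level the cell division list held 21 genes, of which 7 were higher on day 60 than on day 10 and 0 lower, and 5 were higher than on day 30 and 0 lower. Cyclin B (Unigene48756), which drives entry into mitosis, had 38 tags on day 60 against 3 to 19 on the other days, and survivin (Unigene82003), of the mitotic spindle, 24 against 2 to 7. Proliferating cell nuclear antigen (Unigene90357), the sliding clamp of DNA replication, had its highest count on day 15, with 50 tags against 2 to 13. By day of the highest level, 10 of the 21 genes stood on day 15 and 9 on day 60.

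Of the 6 mitochondrial members of the ribosomal list, 4 were higher on day 15 than on day 10, among them L41 (Unigene88396), 4.81-fold (95% interval 3.57 to 6.61), and L12 (Unigene89745), 4.73-fold (3.31 to 6.94). The 8 cytosolic members had a median of -0.04, with 0 higher and 0 lower. Cytochrome c oxidase subunit IV (Unigene85613) rose 11.6-fold (10.1 to 13.4) in the same comparison, and the mitochondrial import translocase TIM44 (Unigene82768) fell at least 89.2-fold, so that proteins of mitochondria did not all move together. In the extracellular matrix list at 1 scaled TPM or more, 6 of 18 genes were lower on day 30 than on day 20 and 0 higher. The nacre list held 7 genes at that level, of which 5 fell from day 10 to 15, and the prism list 3, all of which fell from day 10 to 15, rose from day 20 to 30 and fell from day 30 to 60. Tags of almost a single base after CATG made up 2.10% of the listed tags on day 10, 5.82% on day 15, 3.49% on day 20, 5.36% on day 30 and 2.30% on day 60. These shares depend on Unigene51171, which is counted in the listed tags. In the same order the tags numbered 19587, 56526, 46724, 32200 and 16535, beside 530750, 604456, 534343, 479908 and 495290 listed tags without that unigene.

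Days 10 and 30 shared 51 genes above the other 3 days. Tags of 1 library carried over into the other would keep a single ratio between the libraries, but the interval of the ratio excluded the median ratio of 0.830 in 35 of the 51 genes (68.6%), and the ratios ranged from 0.124 to 3.92. Sequence differences at the tag site in the animals of the other days would leave further sites of the same genes in place. Of 15 genes with a further site 2 (13.3%) kept it on another day. The 51 genes were chosen for low counts over all their sites on the other days, however. A gene that kept a further site thus tended to be left out, and this count cannot decide the question. Animals or tissue of days 10 and 30 that differed from the others for reasons other than the day, such as a larger share of mantle edge in the graft or another stage of an animal's own cycle, remain a possible explanation for the 51 genes, and with 1 library per day they cannot be told apart from the day itself.

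Day 15 held the most genes that peaked on 1 day. Apart from Unigene51171, day 15 had the most listed tags (604456, against 479908 to 534343). This was argued against by thinning to 479908 tags without that unigene, after which 200 genes peaked on day 15 and 125 on day 20. Thinning left more genes listed on day 15 (11533, against 8794 to 10450 on the other days), but among the 1699 genes of at least 10 scaled TPM on some day that were listed on every day, 108 peaked on day 15 and 72 on day 20, the next highest, which argues against the number of listed genes as the whole cause. Less complete cutting at the 3′-most site was argued against by the 173 genes that peaked there with tags of that site alone. More ciliated or sperm cells in the day 15 sample may be a part of the cause. Of the 5 members of the sperm and motile cilia list at 10 scaled TPM, 3 peaked on day 15. At 1 scaled TPM or more, 12 of 13 members (92.3%) were highest on day 15. That compares with 26.4% of all 9515 genes of that level and 39.8% of those with a protein match. The members under 10 scaled TPM reached 1 scaled TPM on day 15 alone, with 6 to 27 tags that day and 0 to 3 on others. Their highest day was thus fixed by the filter, and the 92.3% cannot weigh this explanation by itself. All 9515 genes passed the same filter, but how many did so on 1 day alone was not counted. Ciliated cells are also a part of molluscan epithelia such as the gill and mantle, and no list parted them from sperm. The list's most abundant member, dynein heavy chain 5 (Unigene82585), reached 78.9 scaled TPM, and the share of the 203 peaking genes that such cells account for was not tested.

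Unigene51171 took the largest share of listed tags in each library, and 99.968% of its tags were the single sequence CATGGTTAATCAAAGGGAAGA, with 1918730 copies. This tag was at CATG site 2 from the 3′ end of the unigene. Without Unigene51171, 83.2% to 87.6% of the listed tags of each library were at the 3′-most site. A candidate explanation is that the main tag of Unigene51171 differs by 1 base from the site of the unigene it was given to, so that the tag comes from another transcript. Of 51 possible variants of 1 base, 3 were listed (A14C with 265 copies, A14G with 281 and A14T with 69), all at 1 position, whereas 10 of the 11 other most abundant tags (26411 copies or more, tags of almost a single base apart) had variants at 15 or more of 17 positions. The exception was the tag of ribosomal protein L9 (Unigene23715), also with variants at 1 position. Among the 51 other tags of 5000 copies or more, again with tags of almost a single base apart, 6 had variants at no more than 1 position, so that the pattern is not peculiar to this tag, and whether these 6 differ from their sites too was not tested. No biological explanation was tested, and the changes of Unigene51171 between days are those of this tag, whatever its transcript.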
